A study of Lactiplantibacillus plantarum with 8 samples.

How the data were processed

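The data are 8 spotted 2-colour DNA microarrays of Lactiplantibacillus plantarum WCFS1, a lactic acid bacterium that ferments many sugars. Per the labels, cultures grew in batch on a chemically defined medium with 1 sugar and were harvested at an optical density of 1.0. Each array compared RNA from cells grown on mannose, sucrose, fructose or lactose with RNA from cells grown on glucose. The design stated for the series does not name lactose, which appears only in the labels of the 2 lactose arrays, so what these hold rests on those labels. Each of the 4 sugars had 2 arrays, with the dyes exchanged between them. The labels number the RNAs of each sugar 1 and 2, and arrays with the same number name the same glucose RNA. They do not say whether the numbers stand for separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

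Per the file headers, the authors quantified the Cyanine 3 and Cyanine 5 scans with ImaGene and deposited 1 combined file per array. Per the file headers, the deposited intensity values are ImaGene's quantification of spot signal and local background, with no background subtracted and no normalization. Quality codes mark spots as empty in both channels or as failing a test of shape. A deposited value table also gives 1 log2 ratio per spot and array. Recomputing it showed that the authors' log2 ratios are the background-subtracted mean of the sugar channel over that of the glucose channel. The recomputed values differed from the table by a median of at most 3.04e-07 log2 units on any array. The table is turned by the labelled dyes so that glucose is the denominator. It is not centred, and its column medians ran from -0.58 on fructose replicate 2 to 0.38 on lactose replicate 1.

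Every array held 6912 spots in 24 printed blocks. Of these, 5888 spots carried 1 of 2916 locus tags, the systematic gene numbers of this strain. There were 2888 tags with 2 spots and 28 tags with 4 spots. The other 1024 spots, such as spot buffer, were left out of all tests. The array files do not pair tags with gene names. The reference table given for this organism, assembly ASM991365v1 of another strain, matched 0 of the tags. Genes are therefore reported by tag, and for each comparison at most 2 tags in each direction are printed. For the same reason the 26 gene lists fixed in advance, and their set tests, were not run.

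Background was corrected with normexp at an offset of 50 on the mean signal and median local background, in limma 3.58.1 under R 4.3.3. Log2 ratios were normalized by loess within each array, with weight 0 for spots that were not tags or that failed the shape test. Shape-failed spots were left out, and empty spots were kept. Spots of 1 tag were averaged. limma's linear model was fitted to the log2 Cyanine 5 over Cyanine 3 ratios of all 8 arrays, with 1 coefficient per sugar, coded by dye orientation, and 1 dye term per tag. The fit left 3 residual degrees of freedom for a tag measured on every array. The spread of a tag is shared by all sugars, so the arrays of 1 sugar also enter the errors of the others. Moderated tests were two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. A sugar was tested for a tag only where both of its arrays measured that tag, a filter chosen after seeing the data. Differences between sugars were contrasts of the coefficients. Levels per channel were taken after loess and Aquantile scaling and are given as log2 values.

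The naming rule took tags past the threshold with 1 sign on both arrays of a sugar. It listed the 12 with the highest and the 8 with the lowest ratio. Where fewer than 5 passed, it took the 5 with the smallest p. For each pair of sugars it took the 3 most different in each direction. Its parts on gene lists could not be applied. Only extremes of these lists are printed, for the reason above.

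The median tag spot was between 1.90 and 5.23 times its local background, by array and channel. The number of arrays limits the precision. Shape-failed spots made up between 13.5% and 29.7% of the tag spots of an array, and empty spots between 6.13% and 36.4%. The ratios of duplicate spots correlated across tags at 0.50 to 0.66 on the mannose and sucrose arrays, and at 0.79 to 0.90 on the fructose and lactose arrays. Tags are not independent replicates.

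The fit was tested on simulated arrays with 200 changed tags per sugar and the measured spread. Of the changed tags tested at 1 log2 unit, it recovered 83.3% for mannose, 77.2% for sucrose, 92.5% for fructose and 83.9% for lactose. At 2 log2 units it recovered at least 98.8% for each sugar. False calls made up between 3.4% and 11.4% of all simulated calls. The simulated arrays had 1 spread per tag, whatever the sugar.

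This rule, the model and a first set of alternatives were fixed before the data were examined. These alternatives covered the dye term, a block for the replicate number, background correction, normalization, the deposited log2 values, dim tags, the variance prior, a size threshold and leaving out each array. Further alternatives, chosen after seeing the data, covered shape-failed spots, tags on 1 array, block-wise loess, the direction of the ratios, the mannose arrays and the 2 sets of arrays fitted apart. Runs of neighbouring tag numbers were also defined after seeing the data. A run held at least 3 tags past the threshold with 1 sign, with at most 1 tested tag that did not pass between neighbours. Its test permuted the calls over the tested tags 10000 times. Figures were drawn with matplotlib 3.10.9.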

Results

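Transcript levels of 2916 tags were compared between glucose-grown Lactiplantibacillus plantarum and cells grown on 4 other sugars, to ask which genes respond to the sugar supplied. Mannose and fructose are single sugars like glucose. Sucrose joins glucose to fructose, and lactose joins galactose to glucose. Each sugar was measured on 2 arrays, so every ratio below rests on n = 2. Between 1792 and 2145 tag spots were empty on the mannose and sucrose arrays, against 361 and 1758 on the fructose arrays and 564 and 693 on the lactose arrays. The number of tags tested was 2217 for mannose, 2284 for sucrose, 2663 for fructose and 2588 for lactose.

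The direction of the ratios is not settled. Some arrays with the sugar in the same dye, of different sugars against glucose, opposed each other across tags. Sucrose replicate 1 and lactose replicate 2 correlated at r = -0.33, and sucrose replicate 2 and lactose replicate 1 at r = -0.37. The other pairs with the sugar in the same dye ran from -0.26 to 0.40. Over spots with no quality code the sucrose and lactose pairs were at -0.46 and -0.45. All values below therefore follow the labelled channels, as the authors' deposited table does, and "labelled" marks this. If the channels of a sugar were labelled the wrong way round, every sign for that sugar turns, and its sizes, errors, p-values and total count stay as they are. For a pair of sugars, turning both exchanges the counts in each direction, and turning 1 changes the test, so those counts are given for each pair.

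**Figure D1:**
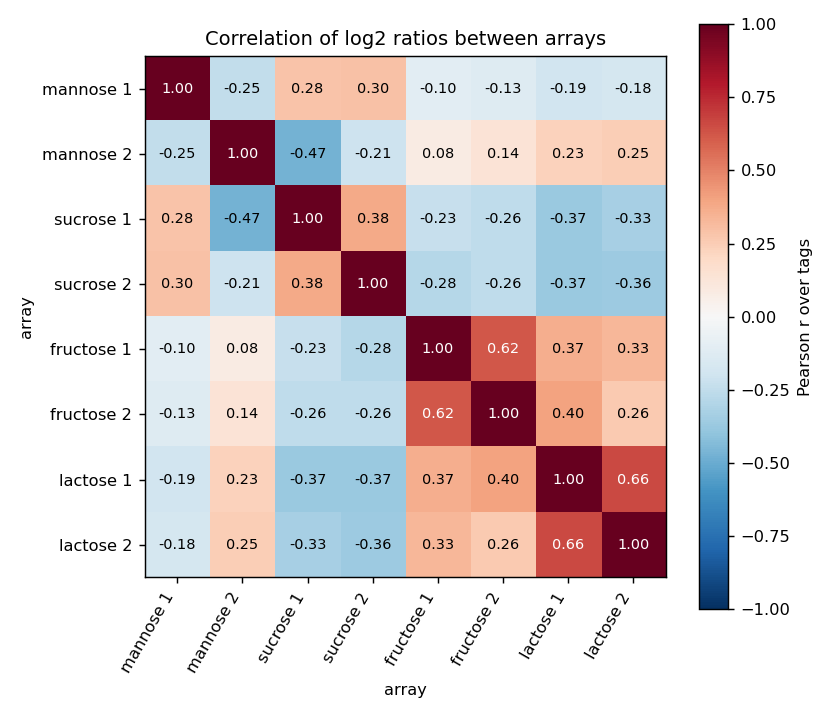
Pearson correlation across tags of the log2 ratios, labelled sugar over labelled glucose, for each pair of the 8 arrays. The fructose arrays correlate at 0.62, the lactose arrays at 0.66 and the mannose arrays at -0.25. Sucrose arrays lie between -0.37 and -0.23 against fructose and lactose arrays. Simulations that split the spread equally between the sugar RNA and a shared glucose RNA gave fitted ratios a correlation of 0.50 between sugars. That value follows from the setting, and within-sugar differences, at -0.16 to 0.08 between sugars, did not show sharing of that size.

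In the sucrose comparison the highest ratios among tags past the threshold belonged to lp_0286 and lp_2780. lp_0286 was 19.6-fold higher in the channel labelled sucrose than in that labelled glucose (log2 ratio 4.29 ± 0.24 SE, n = 2, limma adjusted p = 0.00125). lp_2780 was 11.6-fold higher (3.54 ± 0.20, limma adjusted p = 0.00077). The lowest ratios were those of lp_0577, at -3.51 ± 0.36 (limma adjusted p = 0.00436), and lp_0576, at -3.21 ± 0.30 (adjusted p = 0.00234). Each SE comes from the spread shared by all sugars, not from these 2 arrays alone. On sucrose replicates 1 and 2 lp_0577 was at -2.51 and -4.51, and lp_0576 at -2.71 and -3.71. These 2 tags formed a run of 3 neighbouring tags, all lower in the channel labelled sucrose, with a median log2 ratio of -3.21. A further run of 3 had a median of -1.99. Its tags were at -3.40 to -2.17 on replicate 1 but at -1.07 to -0.92 on replicate 2. Without sucrose replicate 2 neither lp_0577 (-2.61) nor lp_0576 (-2.74) passed, and without sucrose replicate 1 lp_0577 was at -4.41. lp_0286 had no test with either sucrose array or either fructose array left out. With no background correction the log2 ratio was 3.29 for lp_0286 and 2.81 for lp_2780. lp_0286 and lp_2780 did not pass with the deposited log2 values (4.45 and 3.41) or with shape-failed spots kept (4.30 and 3.42).

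In all, 19 of 2284 tags passed the threshold for sucrose, 10 higher and 9 lower in the channel labelled sucrose (9 higher and 10 lower with the sign turned). All 19 had the same sign on both arrays and a size of at least 1 log2 unit. Runs held 6 of the 19 tags, against a mean of 0.0045 over 10000 permutations (permutation p = 1e-04, the smallest they can give). The deposited log2 values, which are not centred, called 5 tags higher and 7 lower. With either mannose array left out, 201 tags passed, and with either fructose array left out 7. Without sucrose replicate 1 the count was 7, and without sucrose replicate 2 it was 3.

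The fructose comparison gave the most tags. lp_2703 was 22-fold higher in the channel labelled fructose (4.46 ± 0.43 SE, n = 2, limma adjusted p = 0.00382). lp_0577, which had the lowest ratio in sucrose, was 16.9-fold higher (4.08 ± 0.36, limma adjusted p = 0.00109). The lowest ratios past the threshold were -2.95 ± 0.28 for lp_2771 (limma adjusted p = 0.0066) and -2.39 ± 0.21 for lp_3679 (adjusted p = 0.00109). The run of 3 tags around lp_0577 had a median of 3.86 in fructose. lp_2703 lay in a run of 8 tags with a median of 2.51, and lp_2771 in a run of 3 with a median of -1.34. Without fructose replicate 1, lp_2703 (4.13) and lp_3679 (-2.09) no longer passed. Without fructose replicate 2, lp_2703 (4.79), lp_0577 (3.68) and lp_3679 (-2.69) no longer passed. lp_2771 had too few arrays left to be tested with either of them left out.

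For fructose 175 of 2663 tags passed, 120 higher and 55 lower in the channel labelled fructose (55 higher and 120 lower with the sign turned). All 175 had the same sign on both arrays, and 127 reached 1 log2 unit. There were 17 runs, 14 higher and 3 lower, which held 76 tags, against a mean of 2.76 over 10000 permutations (permutation p = 1e-04, the smallest they can give). The deposited log2 values called 10 higher and 8 lower. With either mannose array left out, 478 tags passed, with either lactose array left out 57, without fructose replicate 1 13, and without fructose replicate 2 0 in limma, with 256 at an unadjusted p under 0.05.

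**Figure D2:**
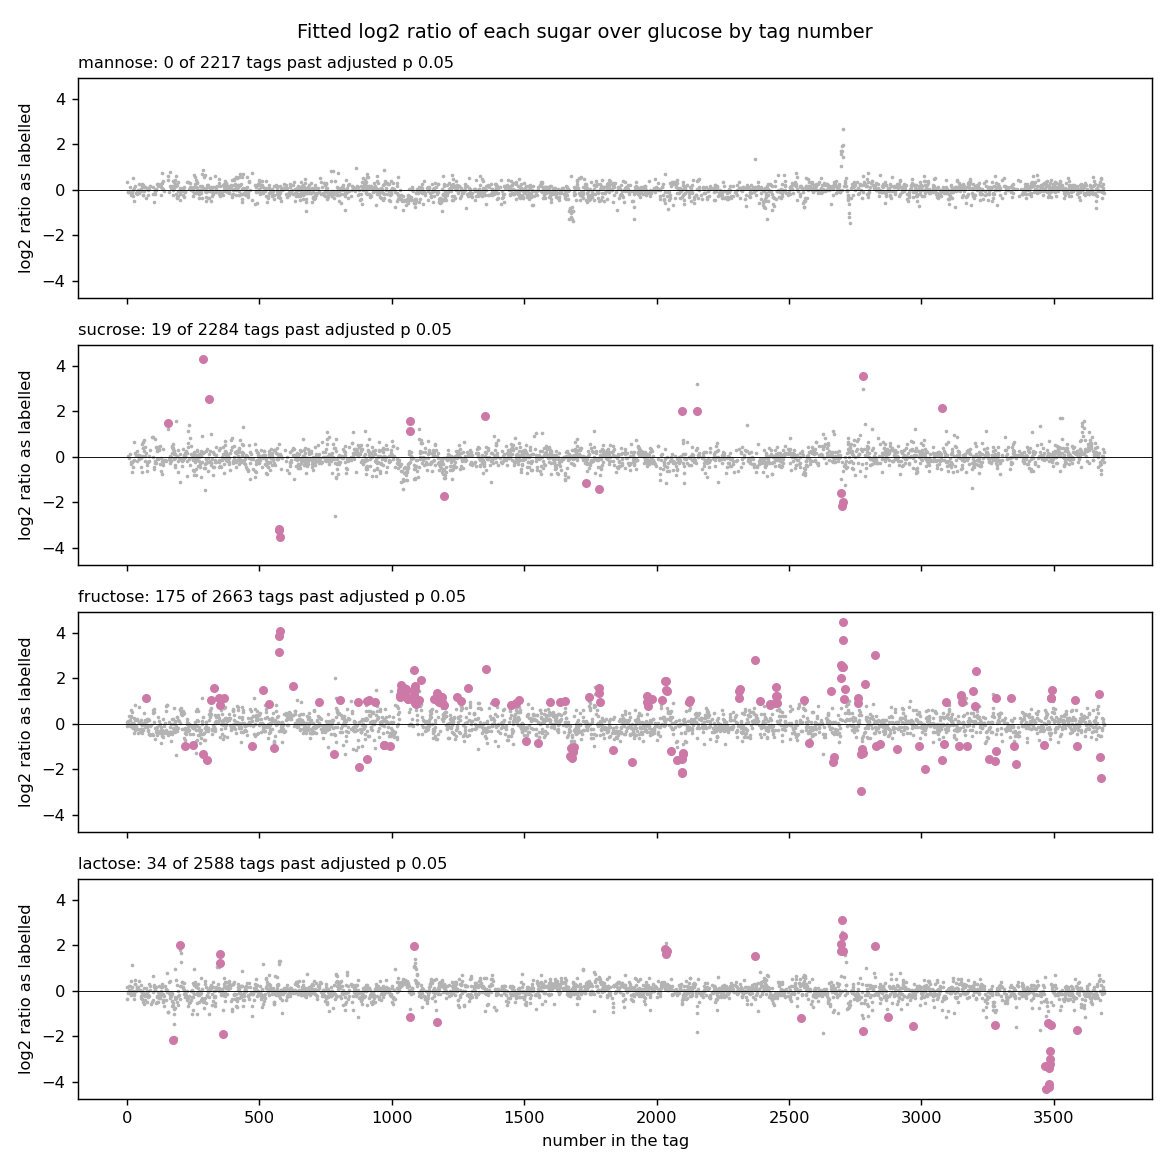
Fitted log2 ratio of labelled sugar over labelled glucose (vertical axis) by the number in the tag (horizontal axis), 1 panel per sugar. Grey points are tested tags, and coloured points are tags past adjusted p 0.05: 0 for mannose, 19 for sucrose, 175 for fructose and 34 for lactose.

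In the lactose comparison, named only in the labels of its arrays and not in the stated design, the largest ratios were negative. lp_3469 was 19.7-fold lower in the channel labelled lactose than in that labelled glucose (-4.30 ± 0.19 SE, n = 2, limma adjusted p = 0.000113). lp_3481 was 18.6-fold lower (-4.22 ± 0.24, limma adjusted p = 0.000113). With no background correction the log2 ratio was -2.98 for lp_3469 and -3.17 for lp_3481. The folds thus depend on the background taken from the dim channel. That channel was at 8.46 and 8.75 for lp_3469 and at 9.11 and 9.21 for lp_3481, within the range of the other arrays. The folds are therefore not exact sizes. Both tags were empty on at least 1 array and were not tested among tags above background on every array. lp_3481 lay in a run of 8 tags, all lower, with a median of -3.10. The median of that run was 0.03 over 7 tags measured in mannose, 0.10 over 4 in sucrose and -0.24 over 6 in fructose, and none of these passed there. The highest ratios among tags past the threshold were those of lp_2701, at 3.12 ± 0.32 (limma adjusted p = 0.00528), and lp_2704, at 2.41 ± 0.29 (adjusted p = 0.00615), which lay in 1 run of 3 tags. lp_2701 did not pass without lactose replicate 2 (2.47) or without the dye term (3.12), and was at 3.78 without lactose replicate 1. lp_2704 did not pass without lactose replicate 1 (2.54) or replicate 2 (2.29).

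For lactose 34 of 2588 tags passed, 14 higher and 20 lower in the channel labelled lactose (20 higher and 14 lower with the sign turned). All 34 had the same sign on both arrays and a size of at least 1 log2 unit. The 3 runs held 14 tags, against a mean of 0.0162 over 10000 permutations (permutation p = 1e-04, the smallest they can give). Among tags above background on every array 12 passed, 8 higher and 4 lower. With either mannose array left out, 167 tags passed, with either fructose array left out 18, without lactose replicate 1 8, and without lactose replicate 2 7.

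The channel levels show where these ratios arose. lp_3469 was at 12.81 and 12.99 in the channel labelled glucose of lactose replicates 1 and 2. In every other channel that measured it, lp_3469 lay between 7.79 and 9.07, glucose channels included. lp_3481 likewise was at 13.33 and 13.43 there and between 7.61 and 9.21 elsewhere. lp_2771 was at 14.41 and 14.33 in the channel labelled glucose of fructose replicates 1 and 2, and at 11.86 or below in all other channels that measured it. lp_0577 was at 10.16 and 10.58 in the channel labelled glucose of the fructose arrays and at 13.40 to 14.96 in the other glucose channels. On the sucrose arrays it was the channel labelled sucrose that stood low for lp_0577, at 12.29 and 9.97. For other tags the channel labelled glucose of the sucrose arrays stood apart from the other glucose channels. lp_2703 was at 14.44 and 14.41 there and at 9.42 to 11.37 in the others. lp_2780 was at 10.11 and 9.84 against 11.66 to 12.87, and lp_0286 at 9.42 and 9.44 against 11.53 to 13.29. For lp_2780 and lp_0286 the channel labelled sucrose also lay above every other channel labelled with a sugar.

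**Figure D3:**
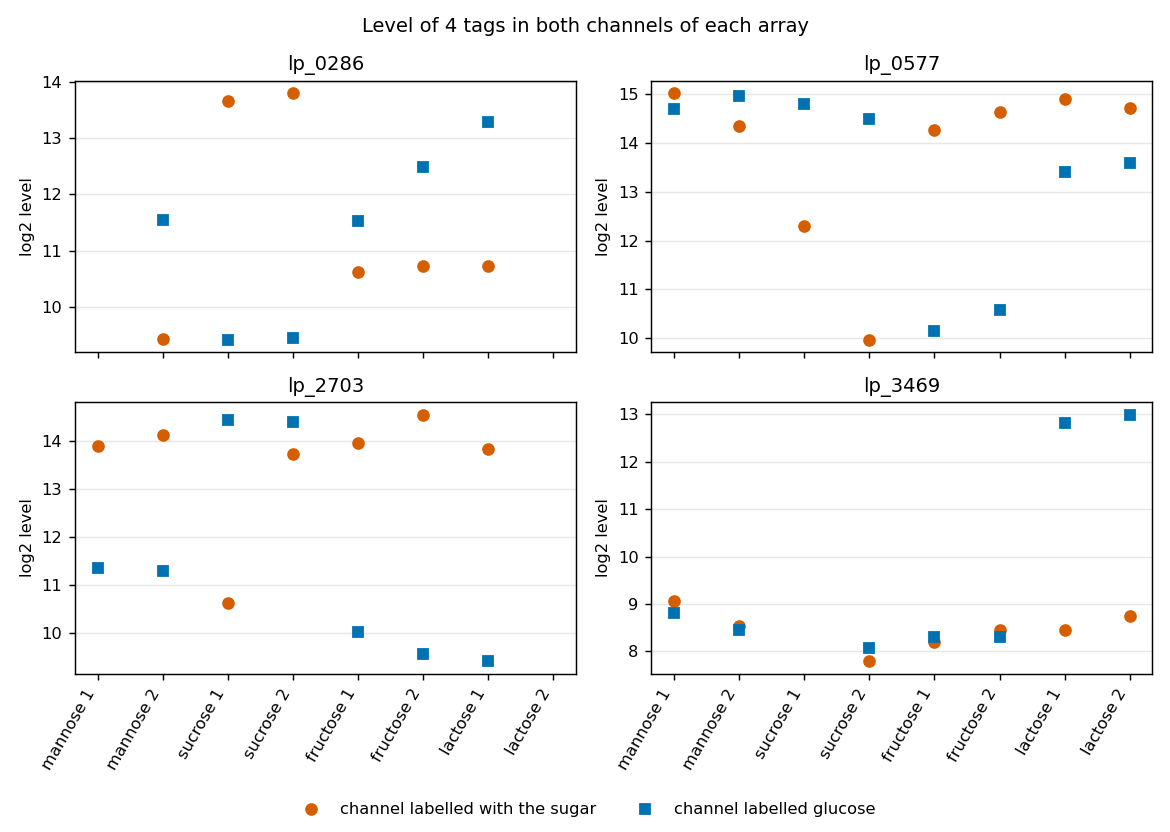
Log2 level of 4 tags in the channel labelled with the sugar (circles) and the channel labelled glucose (squares) of each array, after loess and Aquantile scaling; an array is blank where the tag's spots failed the shape test. lp_3469 is high in the glucose channels of the lactose arrays, at 12.81 and 12.99, and at most 9.07 elsewhere.

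For mannose 0 of 2217 tags passed in limma. At an unadjusted p under 0.05 there were 119, where chance gives 111. The 2 highest ratios among the 5 smallest p-values were 1.98 ± 0.32 SE for lp_2702 (limma adjusted p = 0.125, n = 2) and 1.70 ± 0.22 for lp_2697 (limma adjusted p = 0.0717). lp_2702 was higher in the channel labelled mannose on both arrays, by 1.74 and 2.22, and lp_2697 by 1.39 and 2.01. Both tags lay in the run of 8 tags found in fructose, where its median was 2.51. As labelled, the median of that run was 1.63 over 8 tags in mannose, where 0 passed. It was 1.75 over 7 tags in lactose and -1.40 over 6 in sucrose. The ratios of the mannose arrays opposed each other across 2225 tags, at r = -0.25, against 0.38 for sucrose, 0.62 for fructose and 0.66 for lactose. Median centring in place of loess called 4 tags, all higher in the channel labelled mannose. Over the alternatives the limma adjusted p rose to 0.369 for lp_2697 and to 0.442 for lp_2702. With mannose replicate 1 or 2 left out, the log2 ratio was 1.69 or 1.71 for lp_2697 and 1.66 or 2.29 for lp_2702. A lone mannose array adds no spread of its own, so passes and counts from these fits rest on the spread of the other sugars. lp_2702 passed with median centring (limma adjusted p = 0.0407). lp_2697 also passed with either sucrose array left out, with no background correction (0.0463), with median centring (0.0407), among tags above background on every array (0.0359), with a trended, robust prior (0.023) and with tags on 1 of 2 arrays kept (0.0441). With mannose replicate 1 left out 63 tags passed, and with mannose replicate 2 left out 145. With either sucrose array left out, 4 passed.

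Sucrose and fructose were then compared with each other, to find tags that respond to 1 of them more than to the other. As labelled, 83 of 2110 tags differed, 28 higher in sucrose and 55 in fructose. lp_0577 differed by -7.59 log2 units (limma adjusted p = 0.000233). lp_0286 differed by 5.63 (limma adjusted p = 0.000913). With 1 of the 2 sugars turned, 7 tags differed, the ratio for lp_0577 was 0.57 (limma adjusted p = 0.683) and that for lp_0286 was 2.96 (limma adjusted p = 0.0341). With either mannose array left out, the labelled count was 381, and with either lactose array left out 48. It was 18 without sucrose replicate 2, 11 without fructose replicate 1 and 9 without fructose replicate 2.

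Sucrose and lactose differed as labelled in 48 of 2042 tags, 25 higher in sucrose and 23 in lactose, and in 2 with 1 sugar turned. lp_2780 was higher in sucrose by 5.31 (limma adjusted p = 0.000455), and lp_2701 higher in lactose (difference -5.28, limma adjusted p = 0.00209). With 1 sugar turned these became 1.77 for lp_2780 (limma adjusted p = 0.104) and 0.97 for lp_2701 (limma adjusted p = 0.879). The deposited log2 values called 7 tags higher in sucrose and 10 in lactose. The labelled count was 257 with either mannose array left out and 27 with either fructose array left out. It was 19 without sucrose replicate 2, 10 without lactose replicate 1 and 15 without lactose replicate 2.

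Fructose and lactose differed as labelled in 8 of 2413 tags, all 8 higher in fructose. They included lp_3469, by 4.32, and lp_3481, by 4.30 (limma adjusted p = 0.00139 for each). With 1 of these sugars turned 156 tags differed, 91 with a positive and 65 with a negative sum, and lp_3469 was at -4.28 and lp_3481 at -4.15 (limma adjusted p = 0.000539 for each). With no background correction 18 tags were higher in fructose and 13 in lactose, and the deposited log2 values called 1 tag, higher in lactose. With either mannose array left out, 175 differed. The count was 4 without fructose replicate 1, 3 with either lactose array left out, and 0 in limma without fructose replicate 2, with 136 at an unadjusted p under 0.05.

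Mannose differed as labelled from sucrose in 8 of 1899 tags, all higher in mannose, from fructose in 11 of 2048 tags, 6 higher and 5 lower, and from lactose in 10 of 1981, 9 higher and 1 lower. lp_2703 was higher in mannose than in sucrose by 4.92 (limma adjusted p = 0.0225). In sucrose its labelled log2 ratio was -3.80 on replicate 1 but -0.67 on replicate 2. lp_0577 was lower in mannose than in fructose (difference -4.23, limma adjusted p = 0.0128). lp_3469 was higher in mannose than in lactose by 4.48 (limma adjusted p = 0.00123). With 1 sugar of the pair turned these counts were 4, 23 and 17. The tags then were at 0.46 for lp_2703 (limma adjusted p = 0.81), 3.93 for lp_0577 (limma adjusted p = 0.01) and -4.12 for lp_3469 (limma adjusted p = 0.00109). Against fructose, median centring gave 4 higher and 6 lower, no background correction 14 and 18, and offset 10 gave 1 and 4. Against sucrose, the deposited log2 values gave 5 higher and 4 lower. Leaving out mannose replicate 1 gave 120 tags against sucrose, 153 against fructose and 51 against lactose. Leaving out mannose replicate 2 gave 34, 261 and 203. Against sucrose, 4 differed with sucrose replicate 1 or either fructose array left out. Against fructose, 0 differed in limma with either fructose array left out, with 245 and 197 at an unadjusted p under 0.05, and 5 with either lactose array left out. Against lactose, 5 differed without lactose replicate 1 and 4 without lactose replicate 2.

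No tag passed with 1 sign in all 4 sugars: the count was 0 in limma among 1566 tags tested in each, with 0 at an unadjusted p under 0.05. Because 0 tags passed for mannose, this count is 0 in whichever direction the sugars are taken and cannot show a lack of shared tags. Over the 8 relative directions of the sugars, at most 3 tags had 1 sign in all of them at an unadjusted p under 0.05. That count came with sucrose alone turned, and with fructose and lactose turned it was 0. Of the 2916 tags, 3 passed in 3 sugars and 20 in 2 sugars. Each of the 3 had 1 sign in fructose and lactose and the opposite sign in sucrose as labelled. Turning sucrose alone, or fructose and lactose together, gave each 1 sign in all 3 sugars, so these tags do not tell the 2 options apart.

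Sucrose and fructose shared 10 tags past the threshold, all 10 with opposite labelled signs, where independent lists would share 0.523 in that way. Sucrose and lactose shared 5, all 5 opposite, against 0.0842. Fructose and lactose shared 14, of which 13 had the same sign, 11 higher and 2 lower, where independent lists would share 0.572 higher and 0.366 lower. With 1 sugar of a pair turned, the same and opposite counts trade places. These comparisons name the same glucose RNAs, so 100 simulations of unchanged sugars were run, with glucose RNA shared between arrays of 1 number. The simulated overlap had a mean of at most 0.01 tags for these pairs. The fitted ratios had a covariance of -0.0838 between sucrose and fructose, -0.0857 between sucrose and lactose and 0.0941 between fructose and lactose. The simulated covariances for these pairs were 0.029, 0.0291 and 0.0284. As correlations the fitted values were -0.35, -0.49 and 0.41, and the simulated value was 0.50 for each pair. The simulated values follow from the setting, which split the spread equally between the sugar RNA and the shared glucose RNA. Such sharing by number would also correlate the within-sugar differences between sugars, but these lay at -0.16 to 0.08. The 0.50 is thus no measured value of a shared control, and the 0.41 cannot be judged against it. With 1 glucose RNA per number the controls could not be split, so part of the overlap between fructose and lactose may come from them.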

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

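The tests on the channels of the fructose and lactose arrays, including their sets of tags, and those on the mannose arrays were chosen only after the result was seen. The test on slide neighbours was not. With 2 arrays per sugar, no array was tested as lying far from its group. The bootstrap intervals below resample tags as if they were independent, so they are too narrow where tags move together.

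Tags past the threshold in 2 sugars with opposite labelled signs and a tested difference numbered 10 for sucrose and fructose, 5 for sucrose and lactose and 1 for fructose and lactose. The last tag was at 1.37 in fructose and -1.35 in lactose. A difference between groups put these here.

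On the fructose and lactose arrays the channel labelled glucose stood apart from the glucose channels of the mannose and sucrose arrays. This covered 123 calls, 106 in fructose and 17 in lactose. The glucose channel's median departure exceeded that of the channel labelled with the sugar by 0.78 log2 units (95% bootstrap interval 0.58 to 1.00). A level shift common to both channels would not by itself part them. These calls were chosen for a gap between the channels, so such a shift beside a response stays open. In fructose 20.8% of 106 calls had the channel labelled glucose closer to those glucose channels (interval 13.2% to 28.3%). With other channels of the mannose and sucrose arrays as the reference, the share was at most 33.3% (26.1% to 41.3%). These intervals treat tags as independent, but all calls come from the same fructose arrays, and 76 of 175 fructose calls lay in runs. The intervals are therefore too narrow. If the RNAs labelled glucose are alike, the shares lean against a response to fructose in the labelled direction. Without a valid interval they do not exclude it. For lactose the share was 23.5% of 17 calls (5.88% to 47.1%) but 42.3% of 26 (23.1% to 61.5%) against the mannose arrays alone, and for sucrose 4 of 8 calls, so their labelled directions stay open. Exchanged channel labels on the fructose and lactose arrays stay open and could not be tested apart from the pattern itself: turning both lowered the median spread of the glucose channel by 0.27 log2 units over 153 tags (interval 0.22 to 0.36), which follows once the channel labelled with the sugar is seen to lie closer, and another RNA in the channels labelled glucose stays open as well.

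The mannose arrays opposed each other, and no biological explanation was tested, because the labels give no difference between them beyond the number and the dyes. A dye effect shared by all arrays would correlate their difference with those of the other sugars, but the highest of the 3 correlations was 0.0833. Dim or badly shaped spots did not account for it, since over 1167 tags on unflagged spots r was -0.23 (95% bootstrap interval -0.33 to -0.13). Exchanged labels on 1 mannose array may account for part: of 29 tags at 1 log2 unit or more on both arrays, 21 (72.4%) had opposite signs and 8 the same sign, which leaves it open. When arrays were turned singly, the glucose channel's spread was lowest, at 0.47 over 256 ways, with mannose replicate 2 and the fructose and lactose arrays turned. The spread was 0.51 without turning mannose replicate 2 and 0.78, rank 213, as given. The lowest of 256 ways has no interval and restates the pattern, so it decides nothing here. Mannose replicate 1 correlated with the sucrose arrays at 0.28 and 0.30 and with fructose and lactose arrays at -0.19 to -0.10. For mannose replicate 2 these values were -0.47 and -0.21, and 0.08 to 0.25.

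Tags past the threshold lay in runs of neighbouring tag numbers, as given in the results for sucrose, fructose and lactose. A local defect of the slides would also gather called tags that are neighbours on the slide but far apart in number. Fructose had 37 such pairs, within the central range of 20 to 40 over 10000 permutations, and lactose had 0, within 0 to 4. Genes read as 1 transcript stay open as a biological explanation, which was not tested without an annotation.

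Among spots that carry no tag, 4 of 28 spots of the class named nYIR exceeded the 99th percentile of the spot buffer in mean signal, a signal in data outside the comparisons. Of the spot buffer itself, 6 of 518 did.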

How the results depend on the processing

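The tests with shape-failed spots kept, tags on 1 array kept, block-wise loess, turned directions, no mannose arrays and the array sets fitted apart were chosen after the result was seen. Counts of tags past the threshold within 1.5 times those reported are not listed. No background correction gave 298 tags for fructose, 4 for mannose, 31 between fructose and lactose, 32 between mannose and fructose and 184 between sucrose and fructose. Offset 10 gave 75 for fructose, 22 for lactose, 11 for sucrose, 5 between mannose and fructose, 5 between mannose and sucrose, 30 between sucrose and fructose and 29 between sucrose and lactose. Median centring gave 4 for mannose and 168 between sucrose and fructose. The deposited log2 values gave 18 for fructose, 9 for lactose, 12 for sucrose, 1 between fructose and lactose, 21 between sucrose and fructose and 17 between sucrose and lactose. They gave 0 in limma between mannose and fructose and between mannose and lactose, with 218 and 167 at an unadjusted p under 0.05. Tags above background on every array gave 12 for lactose, 2 for mannose, 2 between fructose and lactose, 26 between mannose and fructose and 0 between mannose and lactose, with 109 at an unadjusted p under 0.05. A trended, robust prior gave 2 for mannose and 125 between sucrose and fructose. Without the dye term 6 differed between mannose and fructose and 4 between mannose and sucrose. Aquantile scaling leaves the ratios as they are, and the size threshold moved no count past 1.5 times.

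The replicate numbers did not pair the arrays: the within-sugar differences correlated between sugars at -0.16 to 0.08, none above 0.1, and 4 of 8 arrays lay closer to their own number. Removing the fitted dye term first forces these correlations towards fixed values. With the replicate number as a block, which leaves the lactose arrays no residual, 57 tags passed for fructose, 19 for lactose, 5 between mannose and fructose, 48 between sucrose and fructose and 28 between sucrose and lactose. Mannose, sucrose and fructose have the same dye orientation for each number, so for them this block cannot be told from the dye term. For these sugars it gives the same fit as leaving out 1 lactose array and is no separate check.

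Keeping shape-failed spots gave 47 between sucrose and fructose. Tags measured on 1 of 2 arrays, when kept, gave 4 for mannose, 17 between mannose and fructose and 18 between mannose and sucrose. Block-wise loess gave 16 between fructose and lactose and 19 between mannose and fructose. Turning 1 sugar of a pair gave 156 between fructose and lactose, 23 between mannose and fructose, 17 between mannose and lactose, 4 between mannose and sucrose, 7 between sucrose and fructose and 2 between sucrose and lactose. Without both mannose arrays 478 passed for fructose, 167 for lactose, 201 for sucrose, 175 between fructose and lactose, 381 between sucrose and fructose and 257 between sucrose and lactose. With mannose and sucrose fitted apart from fructose and lactose, 522 passed for fructose, 186 for lactose and 3 for sucrose. The cause of these changes was not tested. Fewer arrays did not always lower a count. Leaving out both mannose arrays raised it from 175 to 478 for fructose, from 34 to 167 for lactose and from 19 to 201 for sucrose. The main fit shares 1 spread per tag between all sugars, and the mannose arrays, which opposed each other (r = -0.25), enter it. The reported counts and errors of the other sugars thus depend on the mannose arrays. At the same log2 ratio of 4.08, the limma adjusted p of lp_0577 in fructose went from 0.00109 to 4.1e-26 without both mannose arrays. With the sets fitted apart it was 6.02e-71. Values that small need more degrees of freedom than these few arrays leave, so they rest mainly on the spread pooled across tags. The raised counts, also those with either mannose array left out, are therefore no firm gain in tags.

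Leaving out 1 array at a time gave 0 to 478 for fructose, 7 to 167 for lactose, 0 to 145 for mannose and 3 to 201 for sucrose. Between sugars it gave 0 to 175 for fructose and lactose, 0 to 261 for mannose and fructose, 4 to 203 for mannose and lactose, 4 to 120 for mannose and sucrose, 9 to 381 for sucrose and fructose and 10 to 257 for sucrose and lactose. A lone array left for a sugar is assumed to vary like the others. The count with 1 sign in all 4 sugars was 0 in limma under every setting in which it was computed, with 0 to 3 at an unadjusted p under 0.05; where 0 tags passed for mannose, that alone fixes it.

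Tags printed for single sugars kept their sign under every alternative that gave them a value, and 278 of their values kept their side of the threshold, 15 lost it and 12 gained it. Part of this tally could not change, because Aquantile scaling and the size threshold leave these tags as they are. Part repeats a fit, because leaving out either array of another sugar gave the same values. The sizes of the printed tags moved more: with no background correction lp_3469 in lactose went from -4.30 to -2.98. lp_3469 and lp_3481 in lactose and lp_2771 in fructose kept their side of the threshold in each such alternative. These did not include tags above background on every array for lp_3469 and lp_3481, nor the replicate block or either fructose or lactose array left out for lp_2771. lp_0286 gave no value with either sucrose or fructose array left out. The scanner's own processed signals, the brightest probe per gene, a slide or scan-date block and the gene list tests were planned and not run, because the files used hold no such columns, 1 probe ID per gene, or no gene names. Empty spots on the mannose and sucrose arrays limit what dim tags can show.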
